A study of Mus musculus with 2 samples.

How the data were processed

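Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate Gata1, the zinc finger transcription factor that directs red cell development, in mouse cells. Mouse embryonic stem cells were differentiated towards blood as embryoid bodies for 5 days, and cells positive for a Runx1-GFP reporter and a Gata1-mCherry reporter were sorted. Per the labels' protocols, sorted cells pooled from several sorts entered each ChIP after fixation with 1% formaldehyde, with 7 µg of antibody, recombinant histone and mouse RNA as carriers. Libraries were size-selected for fragments of 150 to 400 bp. The series lists 1 Gata1 ChIP library and 1 control library. The control is titled input chromatin, its antibody field names a rabbit IgG, and its description says that too few cells were available for an IgG ChIP, so it was treated as input. No processed file of the control was analysed here.

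The authors deposited a list of 4135 peak positions, each with a chromosome, a start and an end. It has no header, and it carries no score, height, fold enrichment, p-value or summit. Every interval is 400 bp wide, so the width had been set to 1 value before deposit. Per the submitters' processing notes, the tools were Bowtie2 2.0.6 and MACS2 2.0.10 and the build was mm10. Their settings, the peak threshold, the use of the control and any filter are not given in the sources used here. Read depth is unknown, because the deposited values hold no counts. No interval for a peak's strength could therefore be given, and a gene without a peak may have had binding below the unstated threshold. All precision statements below cover counting of peaks or genes only.

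Gene positions came from a RefSeq table of assembly GRCm38.p6, of which mm10 is another name, and peak positions are printed 1-based. The table gives the start and end of each gene with no strand, exons or sequence. The upstream and downstream ends of a gene could therefore not be told apart, and positions are given relative to the lower-coordinate or higher-coordinate end. 340 gene entries with positions below 3 Mb on an autosome or the X were left out as scaffold coordinates. That left 49640 genes, of which 21792 were protein-coding. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.

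The tests of location and of gene lists, the lists themselves and the rule for named genes were fixed before the data were examined. The comparison of the X with the autosomes and the test of the spacing of peaks were chosen after the peak positions were seen. Peaks were divided into those with a midpoint within 1 kb of either end of any gene, those further inside a gene, and those outside genes. The shares were compared with 1000 random placements of the same number of peaks on the same chromosomes within the annotated span (two-sided permutation test, Benjamini-Hochberg adjustment over the classes). Assembly gaps were not masked. These classes replaced the planned ones of promoter, exon and intron, which needed annotation not used here, and the nearest gene was likewise taken by gene body in place of the planned transcription start. For 15 fixed gene lists, the number of protein-coding genes with a peak midpoint in the gene or within 10 kb of either end was compared with 10000 random lists of the same size, matched on gene length in 20 bins (two-sided permutation test, adjusted over the 15 lists). Of 355 listed entries, 351 matched the gene table, and Hbb-b1, Hbb-b2, Ahsp and Tpsab1 did not match a protein-coding gene there. The smallest p these permutations can give is 0.002 for 1000 placements and 0.0002 for lists. For 1 test of spacing, which used 100 placements, it is 0.02. Shares carry 95% Wilson intervals and peak densities carry 95% exact Poisson intervals. Peaks and genes are the units of all tests. With 1 ChIP library there is no replicate, and no test says how binding varies between cultures.

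The planned motif tests, the relation of motif to peak score and the stricter peak threshold were not run, because they need a genome sequence or a score. The rule named 20 fixed genes, up to 8 genes with a peak from each list that passed, up to 3 from each other list, and the 10 genes with the most peaks. That rule ranked genes by score or width. Since neither separates these peaks, genes were ranked by their number of peaks and then by symbol, and naming the 10 highest peaks was not possible. Other genes named, among them list members without a peak, further members of a list and neighbouring genes, were chosen after their values were seen. Some genes that the rule named are not reported here. Alternatives were the size of the window, the nearest gene only, Fisher's exact test without matching, matching on gene density within 100 kb, protein-coding genes only, a distance of 2.5 kb to a gene end, and any overlap. Further alternatives were added after the data were seen. The list test was tested on simulated data with 25-gene lists among 21792 genes and peaks placed at random. A raw p below 0.05 was found in 2 of 100 simulations without planted peaks, in 73 of 100 with 5 genes given a peak, and in 100 of 100 with 10. The simulated peaks did not gather at gene ends or near each other, and the simulated lists were drawn at random. These rates therefore do not cover lists of clustered genes such as the globin genes.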

Results

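Gata1 occupancy was mapped in sorted Runx1-GFP and Gata1-mCherry positive cells from day 5 embryoid bodies, a population that the series describes as primitive erythroid, the first red cell lineage of the embryo. The data comprised 1 Gata1 ChIP library and 1 input library. The peak list held 4135 non-overlapping intervals of 400 bp, of which 4088 lay on autosomes, 42 on the X, 3 on the Y and 2 on the mitochondrial genome. The smallest distance between neighbouring midpoints was 493 bp and the median was 171 kb. The list was unreplicated and had no measure of strength per peak, so each site is reported only as called or not called.

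The question was where Gata1 was bound in these cells, and the first comparison was with the genes of the blood programme. Genes for the red cell membrane and skeleton, for haem synthesis and iron handling, and for blood transcription factors lay near Gata1 peaks about 4 times as often as random genes of the same length. A peak lay in the gene or within 10 kb of it for 20 of 26 membrane and skeleton genes, 16 of 25 haem and iron genes and 26 of 33 blood transcription factors. Such a peak was found for 0 of 19 mast cell and eosinophil markers and 1 of 22 myeloid and macrophage markers. Neither count was past the threshold against random lists (means 2.99 and 3.11 genes, permutation test, adjusted p = 0.14 and 0.52). Among all 21792 protein-coding genes, 3611 (16.6%) had such a peak. The ratio to random genes depended on the window. For membrane, haem and transcription factor genes it was 4.80, 5.60 and 4.41 with 1 kb, and 2.42, 2.47 and 2.41 with 50 kb. With 50 kb, 2 of 19 mast cell and eosinophil markers (ratio 0.314) and 7 of 22 myeloid and macrophage markers (ratio 1.05) had a peak.

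The membrane and skeleton list had 76.9% of genes with a peak (95% Wilson interval 57.9 to 89.0%), against a mean of 4.94 genes in random lists (ratio 4.05, permutation test, adjusted p = 0.001). Its 20 genes were served by 33 distinct peaks. Sptb, encoding the red cell beta-spectrin, had 4 peaks in its window, 3 of them in the gene. Ank1 (ankyrin), Epb41 (protein 4.1), Dmtn (dematin), Gypc (glycophorin C), Rhag and Icam4 each had 2. Slc4a1, encoding the anion exchanger band 3, had 1 peak within 10 kb, at 102363638 to 102364037 on chromosome 11, inside the gene and 1.44 kb from its higher-coordinate end, and 2 more lay 10.1 and 12.4 kb above that end. Ermap, Aqp1, Slc2a1, Trim58, Xk and Mpp1 had none within 10 kb.

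Of the haem synthesis and iron handling genes, 64.0% had a peak (44.5 to 79.8%), against a random mean of 3.97 genes (ratio 4.03, permutation test, adjusted p = 0.001). The call ended with peaks within 1 kb of a gene end alone (ratio 2.59, permutation test, adjusted p = 0.24). Alas2, encoding the erythroid enzyme that starts haem synthesis, carried 2 peaks in the gene, at 150549575 to 150549974 and 150564674 to 150565073 on the X, where the annotated Apex2 gene overlaps it. Peaks also lay within 10 kb of Alad, Uros, Urod, Cpox, Ppox and Fech, which encode later enzymes of haem synthesis. Fech and Ppox had 3 each, and Uros, Abcb10, Fam210b, Snx3 and Tmem14c had 2 each. One of the Ppox peaks lay inside the neighbouring B4galt3. Tfrc, encoding the transferrin receptor, and the mitochondrial iron importer gene Slc25a37 had no peak within 10 kb.

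Blood transcription factors had a peak in 78.8% of genes (62.2 to 89.3%), against a random mean of 6.83 (ratio 3.81, permutation test, adjusted p = 0.001), with 53 distinct peaks. Zfpm1, encoding the Gata1 cofactor FOG-1, carried 8 peaks inside its 56.0 kb. Gata2 had 4 peaks, 2 in the gene and 2 at 3.15 and 4.05 kb below it. The peak at 88202984 to 88203383 on chromosome 6 lay 9.29 kb from its lower-coordinate end. Gata1 itself had 2 peaks in the gene, at 7968243 to 7968642 and 7971303 to 7971702 on the X. Tal1 had 1 peak in the gene, 0.242 kb from its lower-coordinate end, and 3 more within 50 kb, at 17.9 kb below it and at 24.1 and 39.6 kb above it, of which the first was inside Stil and the last inside Cyp4x1. Klf1 had 1 peak, 0.704 kb below the gene. Runx1, Cbfa2t3, Etv6 and Zbtb16 had 3 each, and Nfe2, Gfi1b, Fli1 and Foxo3 had 2 each. Lmo2 and Myb had none within 10 kb, with the nearest at 64.0 and 35.8 kb.

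**Figure D1:**
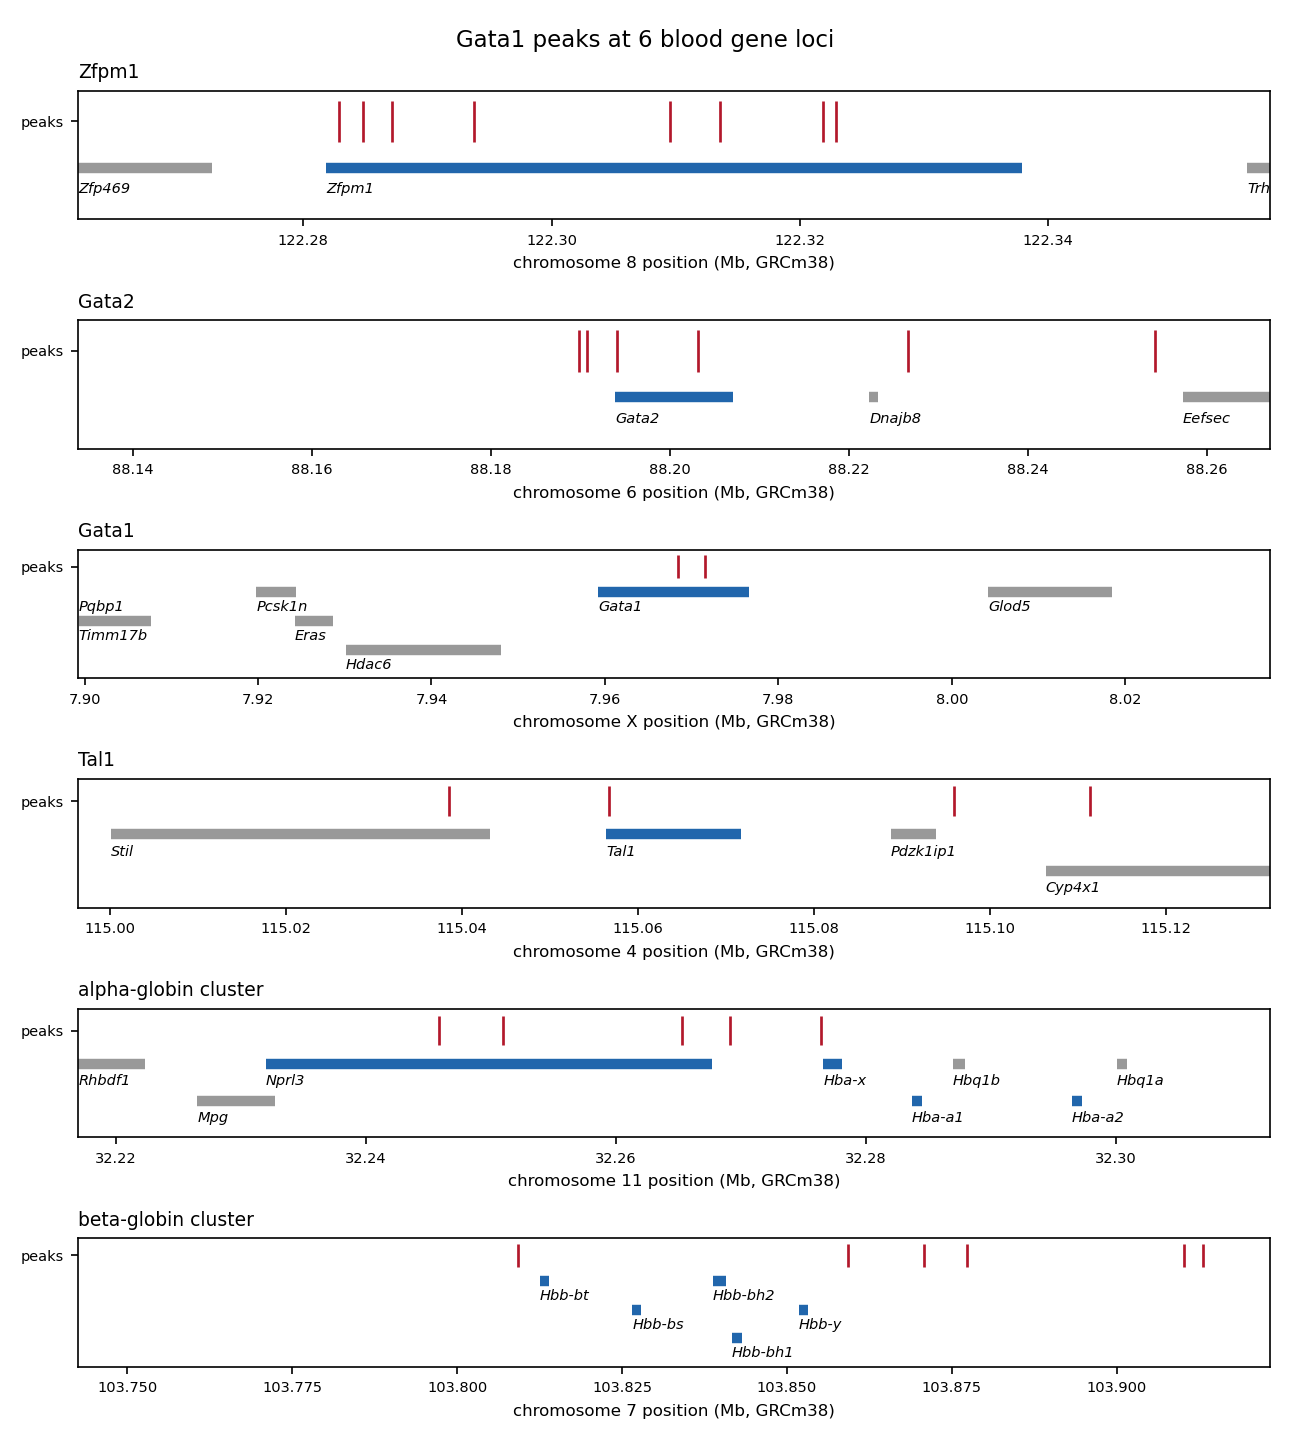
Positions of Gata1 peaks (red lines, drawn at peak midpoints) and protein-coding genes (bars, blue for the named genes and grey for others, genes known only by a number and olfactory receptor genes left out) at 6 loci, with the GRCm38 position in Mb on each horizontal axis. All 8 Zfpm1 peaks lie inside the gene, and 3 peaks at the alpha-globin cluster lie inside Nprl3.

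The globin genes lay near few distinct peaks, placed mostly beside the genes and at a distance. At the alpha-globin cluster on chromosome 11, Hba-x, the embryonic zeta-globin gene, had a peak 0.177 kb below it and another 7.47 kb below it. The first of these was also the 1 peak within 10 kb of the adult gene Hba-a1, at 7.25 kb. The neighbouring Nprl3, whose introns hold some of the known alpha-globin enhancers, carried 3 peaks in the gene, and the 2 peaks below Hba-x also lay within 10 kb of Nprl3. At the beta-globin cluster on chromosome 7, the embryonic Hbb-y had 1 peak at 6.08 kb above it, and 2 further peaks at 17.6 and 24.1 kb above it. The adult gene Hbb-bt had 1 peak, 3.36 kb below it. Hbb-bh1, the other embryonic beta-type gene, had none within 10 kb and its nearest was at 16.1 kb. Of 10 globin genes, 4 had a peak within 10 kb (40%, 16.8 to 68.7%), against a random mean of 0.519 (permutation test, adjusted p = 0.0096). These genes form 2 clusters and are not independent, and the call ended when overlapping windows were counted once (adjusted p = 0.32), when the window was 1 kb (adjusted p = 0.54) and in Fisher's exact test without matching (adjusted p = 0.15). Over all alternatives run for this list, the adjusted p ranged from 0.00075 to 0.54 (permutation tests and 1 Fisher's exact test). With a 50 kb window all 10 genes had a peak.

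Megakaryocyte genes and genes of growth factor signalling were also past the threshold, with smaller ratios. Of 25 megakaryocyte markers, 11 had a peak (44.0%, 26.7 to 62.9%, ratio 2.53, permutation test, adjusted p = 0.0096), among them Itga2b (integrin alpha IIb), Itgb3, Fli1 and Nfe2 with 2 each. Gp1ba, Cd9 and Alox12 had 1 each, and Pf4 and Ppbp had none. The call ended with a 50 kb window (adjusted p = 0.31) and with peaks over 1 kb from every gene end alone (adjusted p = 0.089), and over all alternatives the permutation or exact adjusted p ranged from 0.0037 to 0.31. Of 22 signalling and survival genes, 9 had a peak (40.9%, 23.3 to 61.3%, ratio 2.32, permutation test, adjusted p = 0.044). The cell cycle gene Ccnd3 had 5, the growth-restraining gene Btg2 had 4, Epor, the erythropoietin receptor gene, had 2 and Bcl2l1, encoding the survival protein Bcl-xL, had 2. Kit, the stem cell factor receptor gene, E2f2, Bnip3l and Map1lc3b had 1 each. This list was no longer past the threshold without the genes it shares with other lists (adjusted p = 0.32), on autosomes only (adjusted p = 0.056), or against random lists without chemosensory and unnamed genes (adjusted p = 0.075), and over all alternatives the permutation or exact adjusted p ranged from 0.0015 to 0.7.

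The remaining 9 lists were not past the threshold. For mast cell and eosinophil markers 0 of 19 was found (Wilson upper limit 16.8%; 15.8% by the limit of 3 counts of the total that a count of 0 allows; permutation test, adjusted p = 0.14), and for myeloid and macrophage markers 1 of 22 was found (4.55%, 0.807 to 21.8%, adjusted p = 0.52). The myeloid gene with a peak was Cebpe, and the nearest peak to Spi1, encoding the myeloid factor PU.1, lay 21.4 kb away. Peaks lay near 5 of 24 endothelial markers (permutation test, adjusted p = 0.85), among them Kdr, Egfl7, Esam and Flt1 with 1 each, and the nearest peak to Cdh5, the VE-cadherin gene, was 1027 kb away. Cardiac and early mesoderm genes had 6 of 26 (permutation test, adjusted p = 0.59), including Gata6 with 3, Tbx6 with 2 and Hand2 with 1. The counts were 2 of 22 pluripotency genes (Lin28a and Sox2), 4 of 24 neural genes (among them Gfap, Neurog2 and Nkx6-1), 2 of 22 endoderm and liver genes (among them Foxa1) and 6 of 26 autophagy genes (among them Atg10, Atg4d and Bnip3l). Housekeeping genes had 7 of 25 (28%, 14.3 to 47.6%, ratio 1.86, permutation test, adjusted p = 0.28), B2m, Eef1a1 and Pgk1 among them. All adjusted p-values are from the permutation test over the 15 lists.

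**Figure D2:**
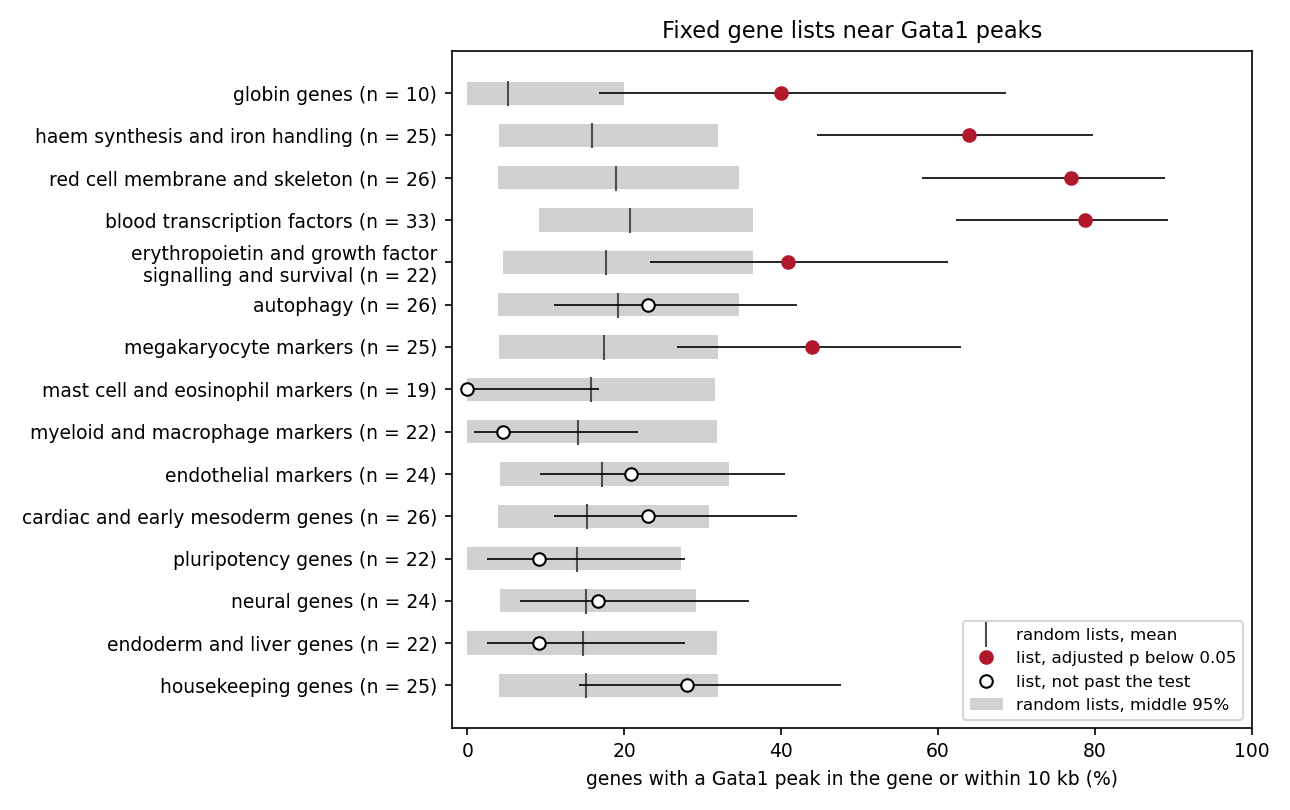
Share of protein-coding genes of each fixed list with a Gata1 peak in the gene or within 10 kb (horizontal axis, %; n is the number of genes found in the gene table). Circles are the lists with 95% Wilson intervals, filled where the adjusted p was below 0.05, grey bars the middle 95% of 10000 length-matched random lists and ticks their mean; the 3 lists of membrane, haem and transcription factor genes lie between 64.0 and 78.8%, clear of the grey bars.

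Among all protein-coding genes, those with the most peaks in their windows were Zfpm1 and Gse1 with 8 each. The other genes that the rule named had 5 each, among 12 genes tied at that number: Ccnd3, Frmd4a, Frs2, Hipk2, Hk1 (hexokinase 1, a glycolytic enzyme), Nol4l, Nprl3 and Plcb3. Of the 3611 protein-coding genes with a peak, 678 had at least 2 and 145 at least 3.

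The second comparison asked where the peaks lay relative to genes in general. Gata1 peaks gathered at gene ends: 1076 of 4133 nuclear peaks (26.0%, 24.7 to 27.4%) had their midpoint within 1 kb of a gene end, 4.00 times the 6.50% of random placements. A further 2100 (50.8%, 49.3 to 52.3%) lay deeper inside a gene, against 45.8% at random, and 957 (23.2%, 21.9 to 24.5%) lay outside genes, against 47.7%. Each of the 3 differences had a permutation adjusted p = 0.002, the smallest the 1000 placements can give. The excess inside genes was no longer present when gene ends were drawn at 2.5 kb (ratio 0.974, permutation test, adjusted p = 0.16). Peaks also lay close to each other more often than random placement gives: 374 neighbouring pairs were within 10 kb, against 72.7 at random (permutation test, p = 0.002) and 88.4 when each peak was placed within its own location class (permutation test, 100 placements, p = 0.02). Both p-values are the smallest that these numbers of placements can give. Every interval was 400 bp wide and the closest midpoints were 493 bp apart. Positions alone cannot tell whether such close peaks are separate sites or 1 region called more than once. The same limit holds for the numbers of peaks per gene.

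The X chromosome held few peaks. Its density was 0.251 peaks per Mb (95% exact Poisson interval 0.181 to 0.339), against 1.70 on the autosomes together, a ratio of 0.147 (two-sided exact binomial test, p = 3.3e-69). The lowest autosomal density was 1.22 (chromosome 14) and the highest 2.88 (chromosome 11). Per 100 protein-coding genes the X had 4.36 peaks and the autosomes 19.9, a ratio of 0.219. The X peaks included those in Gata1 and Alas2. The test treats peaks as independent, which their spacing shows they are not.

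**Figure D3:**
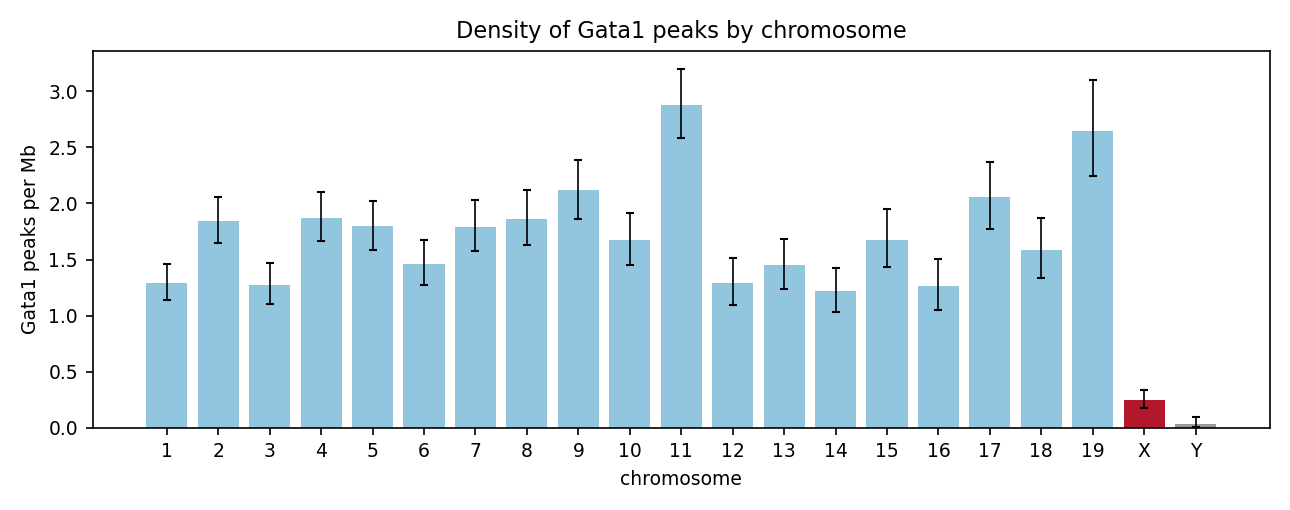
Gata1 peaks per Mb of annotated span (vertical axis) on each nuclear chromosome (horizontal axis), with 95% exact Poisson intervals as error bars and the X in red. The X lies at 0.251 per Mb, and every autosome lies at 1.22 per Mb or above.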

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

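The lists of membrane and skeleton genes and of blood transcription factors kept their direction and stayed past the threshold under every alternative of the gene list test, with ratios to random lists from 2.42 to 5.21 and from 2.41 to 6.03. The haem and iron list did so except with peaks within 1 kb of a gene end alone (ratio 2.59, permutation test, adjusted p = 0.24). Of 6 lists past the threshold, only 2 remained with those peaks alone. The globin list was no longer past it with gene bodies plus 1 kb (ratio 6.92), Fisher's exact test without matching (2.41), peaks within 1 kb of a gene end (7.54), overlapping windows counted once (11.6) and random lists without chemosensory and unnamed genes (3.25). The growth factor signalling list was no longer past it with peaks within 1 kb of a gene end (ratio 1.93), overlapping windows counted once (2.30), autosomes only (2.22), random lists without chemosensory and unnamed genes (2.18) and without genes on other lists (1.85). Neither counting overlapping windows once nor using autosomes only removed a gene from that list, so only the random lists and the adjustment over the other lists differed there. The megakaryocyte list was no longer past it with gene bodies plus 50 kb (ratio 1.44), peaks over 1 kb from every gene end (2.43) and peaks within 1 kb of a gene end (3.30). Alternatives that use only part of the peaks give fewer genes with a peak; otherwise the cause was not tested. The excess of peaks inside genes reversed to a ratio of 0.974 with gene ends at 2.5 kb, which moves peaks between the classes by construction. The excess at gene ends and the deficit outside genes kept their direction and their side of the threshold under the 5 alternatives run for them. The low number of peaks on the X was examined under 1 alternative, per protein-coding gene (ratio 0.219), and the spacing of peaks under 1, placement within the location class (ratio 4.23), and both kept their direction and their side of the threshold. Runs of peaks counted once, overlapping windows counted once, the 2 subsets of peaks by distance to gene ends, autosomes only in the gene list test, autosomes and X only for location, lists without shared genes, random lists without chemosensory and unnamed genes, peaks on the X per gene and placement within the location class were chosen after seeing the data. The stricter peak threshold, the motif tests and the score relation were not run. Depth could not be examined, so a gene without a peak is only one where no peak was called.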

Other observations

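The test of peaks over 1 kb from gene ends was chosen after the peak list was seen and before its own result was; the other tests of explanations, the family test, the test for excess peaks per gene and the direct comparisons of lists were chosen after the peak positions or list counts were known. Chemosensory genes were almost free of Gata1 peaks: 10 of 1109 olfactory receptor genes (Olfr) had a peak within 10 kb, against 63.2 in length-matched random lists (permutation test, adjusted p = 0.011 over 113 families of genes that share a symbol stem), and 1 of 352 vomeronasal receptor genes (Vmn) did, against 32.8 (adjusted p = 0.011). Cytochrome P450 genes (Cyp) had 5 of 99 against 16.6 (permutation test, adjusted p = 0.038), and no other family passed. Members of these families lie in clusters and are not independent, so these p-values are too small. Read mapping in these families was not examined, so a low count means few called peaks and need not mean little binding.

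In an exploratory count against the number expected from gene length (Poisson test over 21792 genes, which ignores the clustering of peaks), 7 genes had an excess past the adjusted threshold. Zfpm1 and Gse1 had 8 each against 0.253 and 0.261 expected (exact Poisson test, adjusted p = 4.6e-06 for both). Plcb3, which encodes a phospholipase C, had 5 (exact Poisson test, adjusted p = 0.012), Nprl3 at the alpha-globin cluster had 5, and Btg2 and Gadd45a, growth arrest genes of a few kilobases, had 4 each (adjusted p = 0.028 for each of these 3). Prkca had 5 (exact Poisson test, adjusted p = 0.0499). Compared directly, the membrane, haem and transcription factor lists together had a peak in 62 of 84 genes. The mast cell and myeloid lists together had one in 1 of 41 (Fisher's exact test, odds ratio 113, adjusted p = 5.3e-15 over 4 comparisons). In the same exact test the odds ratio was 10.7 against endothelial markers (adjusted p = 7.5e-06), 9.39 against cardiac and early mesoderm genes (adjusted p = 7.5e-06) and 4.24 against megakaryocyte markers (adjusted p = 0.0053), leaving out shared genes. These comparisons were chosen after the peak positions or list counts were known, and the first set the highest shares against the lowest. Its large odds ratio follows from that choice. None was matched on length, and neighbouring genes such as the mast cell Mcpt genes were counted as independent, so these p-values are too small. Against length-matched random lists the mast cell and myeloid lists did not pass (permutation test, adjusted p = 0.14 and 0.52).

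Peaks at erythroid and blood genes could reflect chromatin that is open at the ends of any active gene and is recovered whatever the antibody. Peaks over 1 kb from every gene end alone gave 45 of the 84 genes against 10.8 in random lists (ratio 4.17, permutation test, p = 0.0002). Peaks within 1 kb of annotated gene ends were therefore not the only source. Gathering at gene ends reached past 1 kb, so this cut did not remove it. Shares were 26.0% within 1 kb (6.50% at random) and 40.5% within 2.5 kb (14.2% at random). With the same peaks, housekeeping genes had 5 of 25 (ratio 2.32, permutation test, adjusted p = 0.25). Signal around the ends of active genes stays open. Transcript starts inside genes were not annotated, so peaks at such starts counted as far from gene ends. Open chromatin at those starts therefore stays possible. The 3 lists also exceeded the housekeeping genes, of which 7 of 25 had a peak (odds ratio 7.25, Fisher's exact test, p = 8.4e-05). That comparison was chosen after the peak positions or list counts were known and was not matched on length, so it does not exclude activity of any kind. Against length-matched random lists the housekeeping ratio was 1.86 (permutation test, adjusted p = 0.28). The membrane, haem and transcription factor ratios were higher, at 4.05, 4.03 and 3.81. Activity of any kind as a source of part of the excess stays open. Accessibility particular to erythroid genes stays open, since the input was not analysed here. No other group of cells was compared, so no biological explanation was tested.

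The X held 0.147 times the autosomal density of peaks. Fewer genes do not account for this: 38 of 963 X-linked protein-coding genes had a peak, against 162 expected from length-matched autosomal genes (ratio 0.235, permutation test, p = 0.0002), and leaving out chemosensory and unnamed genes gave 37 against 150.1 (ratio 0.247). A hypothesis is that the cells carry 1 X, which would lower its coverage and with it the number of peaks past the caller's threshold. The 3 peaks called on the Y bear on this, but without read depth they do not show that the cells carry a Y. A single X cannot be told apart from fewer bound sites on the X without the read depth of the input, and the ratio of 0.147 alone does not decide it.

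Peaks on the X gathered around Gata1: 7 of the 42 lay in the 500 kb centred on that gene, near Tfe3, Kcnd1, Otud5 and Was besides the 2 in Gata1, where the other 333 windows of the X had a mean of 0.105. This stretch holds 23 protein-coding genes, and among 17 other X windows with at least 10 genes the mean was 0.412 and the highest count 4. Of 85 autosomal windows with as many genes, 6 reached 7 or more (mean 2.92), so gene-dense sequence around Gata1 stays open, since the X windows compared needed only 10 genes and this one was singled out for its peaks. A candidate explanation is extra copies of the Gata1 region from the reporter, which would raise coverage over this block of 7 peaks. How the reporter was built is not given in the sources used here, and the input depth that would show extra copies was not analysed here. Activity of this region in erythroid cells, at Gata1 and its neighbours, stays open as well.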
